A study of Mus musculus with 12 samples.

How the data were processed

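Total RNA of whole ear tissue from homozygous Spade mice and wild-type littermates at 2, 4 and 6 weeks of age was measured on 12 Affymetrix Mouse Genome 430 2.0 arrays, 2 for each genotype and age. Each array carries 45101 probe sets. Per the series design text, the authors isolated RNA with a kit for fibrous tissue, analysed the arrays in GeneSpring GX and R/Bioconductor, and normalized them with GCRMA.

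The log2 values used for all main tests are the GCRMA values as deposited: the authors corrected background, normalized across arrays and summarised each probe set, in a version the labels do not state. These values ran from 2.14, a floor shared by all arrays, to 16.6. The values of the series matrix equal them to within 4.9999e-09 and were used only for that comparison. The intensity values of the per-array files are MAS5 signals on a linear scale, which the authors scaled on each array as deposited, with a trimmed mean of 499.8 to 499.9 as computed here, and each comes with a detection call. They were used for detection calls and as an alternative after a floor of 50 and log2 transformation. A copy of these signals divided by the array median was not used here, and raw scans were not analysed here.

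Probe sets were named from the array annotation given with the data: 34958 named 1 gene, 932 several and 9211 none. For each of 18194 genes the probe set with the highest mean over all arrays among those naming only that gene was kept. The 11984 genes with a value of 4 or more in at least 2 of 12 arrays were tested. Tests used limma 3.58.1 in R 4.3.3, with a mean for each of 6 groups, 6 residual degrees of freedom, moderated variances with a trend on mean level, and Benjamini-Hochberg adjusted p under 0.05. Fold changes are given with the standard error of that fit, and each adjusted p for a gene is from limma. Comparisons were mutant against wild type at each age and on average over ages, the differences between these effects, and wild type at 6 weeks against 2 and 4 weeks. Where MAS5 called a gene absent on all arrays of the dimmer group, its fold is given as at least the fitted value, unless arrays of the brighter group lay at the floor too or were all called absent. Where some of those arrays were called present, the fold is as fitted: wild-type arrays called present for Fcer1a and Oasl2 were 1 of 6 on average, for Ccl12 2 of 6 and for Krt6b 3 of 6, and at 6 weeks 1 of 2 for Fcer1a, Krt6b, Pecam1 and Myh8. A fold given as at least a value assumes that the true dim level was no higher than its GCRMA value. This was not tested. Probe sets called present also lay at the floor of 2.14 on every array, so such a fold may also be too large. With 2 arrays per group, the spread is estimated from all 12 arrays together, and few arrays rather than the probe sets limit precision.

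Of 30 gene lists fixed from skin and ear biology, 27 had at least 5 tested genes, with 538 distinct genes in all. Lists were tested with camera in limma at its preset correlation of 0.01, and also with a correlation estimated within each list and with fry, each adjusted over 27 lists. A list gene's adjustment over the list alone uses only the genes of that list, and that over the lists alone uses the 538 genes. An exact permutation test of each list's mean, exchanging genotype within age over 216 assignments, was added after the data were examined, so its smallest possible p is 0.00926. The comparisons, lists, tests and most alternatives were chosen before the data were examined. The alternatives chosen afterwards were a term for sex from Xist, array weights and the exact permutation. Each array left out in turn was planned, while singling out 2-week mutant replicate 3 for the lists was decided afterwards.

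The rank product criterion named in the design text was computed with an implementation of its own in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, from 1000 permutations. It asks for a 2-fold difference and an estimated false discovery rate under 0.05 per age, or under 0.001 for the ages together. Figures were drawn with matplotlib 3.10.9.

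Genes named in the report follow a rule set before the data were examined. It takes Jak1, the list genes, the 10 highest and 10 lowest fold changes past the threshold in each comparison of genotypes with 1 direction throughout, and the 5 highest and 5 lowest in the other comparisons. From each list described it takes up to 4 members past the threshold and up to 2 that did not pass, by absolute change. Genes named with the rank product counts, those shown in figures, and list genes quoted for a single age were chosen after their values were seen. No predicted gene was among the 77 calls on average.

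Most alternatives changed 1 choice at a time. The choices were the criterion, a 2-fold minimum, no filter or a filter at 6, the mean of a gene's probe sets, all probe sets and MAS5 signals. Further choices were median centring, quantile normalization, the variance prior, the arrays in the fit and each array left out. Array number ranges and replicate numbers were also used as blocks. The rank product criterion changed the test, the fold minimum and the threshold together. Filters, probe set choices and MAS5 signals also changed which genes were tested. The ranges are those of the array numbers in the labels; no processing dates were used here.

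Tests were also tried on simulated data with known changes. On average over ages, 43.2% of genes changed by 0.5 on the log2 scale were called, 80.8% at 1, 95.2% at 2 and 99.2% at 4, and 4.56% of calls were unchanged genes. At 6 weeks the shares were 10.0%, 52.0%, 83.6% and 96.8%, and 5.02% of calls were unchanged genes. The changed genes were picked at random and varied independently, so these shares may be too high for the ear data. There only 4 genes passed at 6 weeks, and Krt6b and Btc, with differences beyond 4 on the log2 scale, did not. The list test, at an unadjusted p under 0.05, called 5 of 5 shifted lists and 0 of 5 unshifted lists. These are too few to measure an error rate. The rank product criterion at 6 weeks called 81.0% of genes changed by 2 and 100% of those changed by 4 when all genes spread alike, with 0 of 181 calls unchanged. With each gene's own spread it called 2.0% and 100%, and 13.6% of 118 calls were unchanged genes. The simulated lists held independent genes, which the lists of co-regulated genes in this tissue are not.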

Results

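Gene expression was measured in whole ear tissue of mice homozygous for the Spade allele and of their wild-type littermates at 2, 4 and 6 weeks of age. The published study of this line describes Spade as a gain-of-function allele of Jak1, the kinase that couples many cytokine and interferon receptors to STAT transcription factors. Homozygous mice are known to develop a progressive dermatitis. Whole ear holds epidermis, dermis, hair follicles, cartilage, muscle, fat and any leukocytes that enter the skin. Total RNA of each sample was hybridised to 1 Affymetrix Mouse Genome 430 2.0 array, which gave 12 arrays in 6 groups of 2. Between 52.3% and 58.1% of the 45101 probe sets on an array were called present. Replicate arrays correlated at r = 0.985 to 0.994 over the 11984 tested genes in 5 groups and at 0.939 in the 2-week mutants. The labels number the samples of a group without naming animals, so p-values measure only the spread between these samples. The number of arrays limits the precision of every value below.

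The first comparison asked which genes differed between mutant and wild-type ears when the 3 ages were averaged, as in the pooled data set of the study's design. Krt84, a hard keratin of hair and nail, was at least 17.5-fold higher in the mutant, with a log2 difference of 4.13 ± 0.46 (SE, 6 arrays per genotype). Mcpt8, a protease of basophils, was 15.1-fold higher as fitted (3.92 ± 0.68), and lay at the floor on all wild-type arrays and on 4-week mutant replicate 1. Chil1, a chitinase-like protein of activated macrophages and epithelium, rose 11.6-fold (3.54 ± 0.45), and Wfdc18, a secreted protein with a protease-inhibitor fold, rose 12.4-fold (3.63 ± 0.58). The epidermal serine proteases Klk6 and Prss27 rose 8.43-fold and 6.61-fold. The aldehyde oxidase Aox4 rose 6.46-fold, and the cyclic nucleotide phosphodiesterase Pde1b rose 6.29-fold. Btc, which encodes the EGF receptor ligand betacellulin, fell by 2.77 ± 0.44 on the log2 scale, the lowest value among the calls. Other genes that fell were Hemgn, known as a nuclear factor of blood progenitors (-1.52 ± 0.22), the potassium channel gene Kcnj16 (-1.14 ± 0.16), and F3, the tissue factor that starts coagulation (-0.90 ± 0.14). Il34, the keratinocyte ligand of the receptor on which Langerhans cells depend, fell by 0.65 ± 0.11. Falls between -0.96 and -0.60 were measured for Tmem35a, Abca5, Cth, Sema3d and Mfsd14b.

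In all, 77 of 11984 genes passed an adjusted p of 0.05 in limma, 64 higher and 13 lower in the mutant, and 42 of these also differed at least 2-fold. Of these genes, 76 had the same direction at all 3 ages; the exception was Ccl12, at -0.30 at 4 weeks. The 2 mutant and 2 wild-type arrays of an age did not overlap, in the direction of the average, for 73 of the 77 genes at 2 weeks, 71 at 4 weeks and 77 at 6 weeks. For genes not chosen by their difference chance gives 16.7% in 1 fixed direction, but these genes were chosen on the same arrays, so the counts describe them and test nothing. Jak1 itself differed by -0.15 ± 0.09 on the log2 scale and did not pass in limma (adjusted p = 0.50). The count was 24 with array number range as a block, 24 without a filter on low values (10 of them among the 77), 40 on MAS5 signals (23 of them among the 77) and 238 with a random replicate block. It was 48 with the mean of probe sets and 43 over all probe sets. Leaving out 1 array leaves the other alone in its group and also changes the pooled error. Without 2-week mutant replicate 2, replicate 3, whose hair list stood apart, was alone. The count moved widely in these fits. It was 1070 without 2-week mutant replicate 2 and 166 without 4-week mutant replicate 1, 35 without 4-week mutant replicate 2, and 2 to 7 without any 1 of the 2 6-week mutants or the 6 wild-type arrays.

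**Figure D1:**
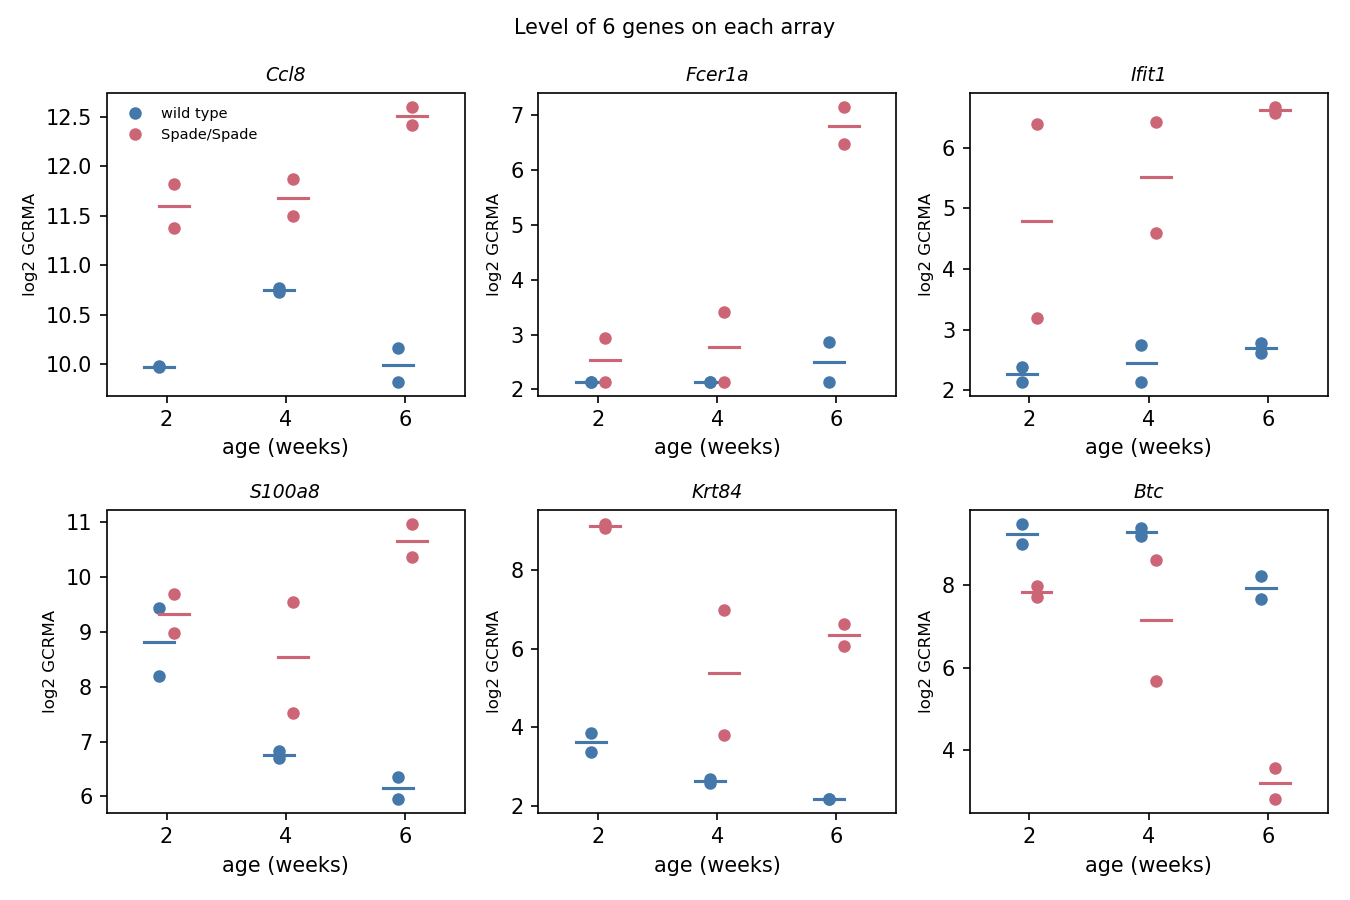
Log2 GCRMA level (vertical axis) of Ccl8, Fcer1a, Ifit1, S100a8, Krt84 and Btc on each array against age in weeks, with a point per array and a bar at the mean of each group of 2. The 2 mutants lie above the 2 wild-type arrays at each age for Ccl8, Ifit1 and Krt84, and below them for Btc, while Fcer1a has a 6-week mutant mean of 6.80 against 2.50 in wild type.

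All 31 measured members of the list of interferon-stimulated genes had a positive average difference, with a mean log2 fold change of 1.13. With an estimated correlation between its genes, camera gave an adjusted p = 0.075. Of these, 9 passed over all genes and 28 passed when adjusted over the list alone. Ifit1, which binds foreign RNA, rose 9.01-fold as fitted (3.17 ± 0.53, at the floor on 2 of 6 wild-type arrays), Usp18, the protease that removes the ubiquitin-like ISG15, rose 7.21-fold (2.85 ± 0.34), the immunity GTPase gene Iigp1 rose 4.13-fold, and Xaf1, a proapoptotic interferon target, rose 2.71-fold. Oasl2, of the oligoadenylate synthetase family, did not pass (3.46 ± 0.70, limma adjusted p = 0.079). Both mutant arrays lay above both wild-type arrays in the mean of this list at all 3 ages. The shift therefore had the smallest two-sided p that an exact permutation of genotype within age can give (0.00926, adjusted p = 0.036 over 27 lists). That adjusted p depends on how many lists tie at the smallest p. Against the single wild-type array of the same array number range, the list's mean differed by 1.03 at 4 weeks and 1.16 at 6 weeks, beside 0.91 and 1.19 against both wild-type arrays.

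All 29 macrophage, monocyte and dendritic cell markers had positive differences, with a mean of 0.73, and 7 passed over all genes and 27 adjusted over the list alone. With an estimated correlation, camera gave this list an adjusted p = 0.072, the neutrophil list 0.092 and the mast cell and basophil list 0.118. Ccr2, the receptor that brings monocytes into tissue, rose 2.39-fold (1.26 ± 0.16), the lectin receptor gene Cd209d 1.93-fold, and the complement genes C1qa and C1qc 1.80-fold and 1.75-fold. Plac8 and Aif1 did not pass (1.27 ± 0.34 and 0.96 ± 0.29). All 7 neutrophil markers were positive, with a mean of 1.58, and S100a8, a subunit of calprotectin that keratinocytes also make, passed at 4.81-fold (2.27 ± 0.36). In that list 4 genes passed when adjusted over the list alone, and Stfa2l1 and S100a9 stood at 3.38 ± 0.67 and 2.49 ± 0.48 without passing over all genes. Of 13 mast cell and basophil markers, Mcpt8 and Fcer1a, the chain of the IgE receptor that binds IgE, passed over all genes and 3 adjusted over the list alone, with a list mean of 0.77. Cyp11a1 and Hdc did not pass, at 0.77 ± 0.31 and 0.66 ± 0.24.

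All 16 genes of MHC class II and antigen presentation were positive, with a mean of 0.50; 4 passed over all genes and 15 adjusted over the list alone. With an estimated correlation, camera gave this list an adjusted p = 0.072. Ctss, the protease that processes the invariant chain, rose 1.73-fold (0.79 ± 0.10), the invariant chain gene Cd74 1.44-fold, and the class I genes H2-D1 and H2-K1 1.33-fold and 1.32-fold. Psmb9 and Tap1, of the class I peptide pathway, did not pass (0.76 ± 0.16 and 0.69 ± 0.14). The 6 Langerhans cell markers had a mean of 0.31, with Cd74 alone past the threshold over all genes and 2 adjusted over the list alone. In that list Epcam and Cd207 stood at 0.68 ± 0.17 and 0.52 ± 0.25 without passing. The 15 T cell and innate lymphoid markers had a mean of 0.45 with no member past the threshold over all genes and 1 adjusted over the list alone. Camera with an estimated correlation gave this list an adjusted p = 0.138 and the Langerhans cell list 0.075. In the T cell list Il7r and Cd3d stood at 0.91 ± 0.27 and 0.67 ± 0.24.

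Of 15 type 2 cytokines, receptors and induced genes, Ccl8, a chemokine for monocytes and type 2 helper T cells, rose 3.23-fold (1.69 ± 0.11, limma adjusted p = 0.0011, the lowest among all genes). Clec10a, a lectin of alternatively activated macrophages, rose 1.89-fold, and 8 of the 15 passed when adjusted over the list alone, 6 of them upward. Camera with an estimated correlation gave an adjusted p = 0.072 for the type 2 list and for the innate cytokine list, and 0.199 for the JAK-STAT list. Il33, an alarmin of the IL-1 family, and the chemokine gene Ccl22 did not pass (-0.78 ± 0.27 and 0.75 ± 0.18). Among 16 innate cytokines and chemokines the monocyte chemoattractants Ccl12 and Ccl6 rose 3.32-fold and 2.44-fold, 5 passed adjusted over the list alone, and the list mean was 0.40. Ccl9 stood at 0.93 ± 0.17 without passing. Il6, which did not pass, lay at or near the floor on all arrays but the 6-week mutants (5.89 and 4.09), so no average fold is given. Of 34 JAK-STAT feedback and target genes, Bcl3, an atypical IκB protein that STAT3 induces, rose 3.56-fold (1.83 ± 0.25). In that list 6 passed when adjusted over the list alone, the mean was 0.21, and the feedback inhibitor gene Socs3 and the transcription factor gene Irf1 did not pass (1.08 ± 0.35 and 0.72 ± 0.16).

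Among epidermal lists, the 24 barrier activation keratins and alarmins had a mean of 1.41. S100a8 passed over all genes and 15 members passed adjusted over the list alone. An estimated correlation in camera gave this list an adjusted p = 0.075, with 0.203 for the proteases, 0.49 for the cornified envelope and 0.65 for the hair list. Krt16 and Krt6b, keratins of wounded and hyperproliferative epidermis, spread widely (4.67 ± 1.11 and 4.47 ± 0.94, adjusted p = 0.11 and 0.089 in limma). Of 25 epidermal proteases and inhibitors, 24 were positive with a mean of 0.38; Klk6 passed over all genes and 6 adjusted over the list alone, while Klk13 and Klk7, proteases of corneocyte shedding, stood at 1.54 ± 0.39 and 0.76 ± 0.16. The 31 cornified envelope genes had a mean of 0.23 with no call over all genes and 4 adjusted over the list alone, among which Lce1m was lower (-1.34 ± 0.25, limma adjusted p = 0.059). The 31 hair shaft and inner root sheath genes had a mean of 0.78, but Krt84 was the single call and the mean was -0.31 without 2-week mutant replicate 3, whose hair list level was 12.1 against 5.58 to 6.61 on the other 2-week arrays.

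The mean of 29 skeletal muscle genes was -0.70, that of 21 cartilage genes -0.50 and that of 16 adipocyte genes -0.37. With an estimated correlation, camera gave an adjusted p = 0.43 for each of these 3 lists. No member passed over all genes, and 2 adipocyte genes passed adjusted over the list alone. The largest values were -1.43 ± 0.72 for Myh2, a fast myosin, -1.21 ± 0.59 for the cartilage matrix gene Ucma and -1.38 ± 0.32 for Thrsp, a regulator of fat synthesis. Myh2 and Ucma had levels of 5.27 and 4.20 in 2-week mutant replicate 3, against 10.3 and 8.36 in replicate 2, so both values rest largely on that array. Without 2-week mutant replicate 3, which held the lowest muscle level, the muscle mean was -0.34, the cartilage mean -0.28 and the adipocyte mean -0.21.

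By camera, 17 of 27 lists shifted on average, 14 up and 3 down, and those are the lists given above. Of 100 splits of the arrays within age, 23 gave at least 17 lists, so this count does not set the genotypes apart from other splits. The exact permutation of genotype within age, chosen after the data were examined, kept 7 of them at an adjusted p = 0.036 each: interferon-stimulated genes, type 2 genes, neutrophil, macrophage, Langerhans cell and T cell markers, and antigen presentation. In each of these 7 both mutants lay above both wild-type arrays at all 3 ages. That separation is what gives the smallest possible exact p, so it is not further evidence. The adjusted p depends on how many lists tie at that smallest p. A list alone there would not have passed over 27 lists. The 7 lists use the same arrays and share genes such as Cd74. For T cell markers the separation at 4 weeks rests on a level of 6.229 in mutant replicate 1 against 6.228 in wild-type replicate 1. For Langerhans cell markers at 2 weeks it rests on 10.05 in mutant replicate 3 against 10.04 in wild-type replicate 2. Through the ties, the adjusted p of the other lists leans on these narrow separations too. The barrier activation and mast cell lists had an adjusted p = 0.056 by that exact test, and the muscle and adipocyte lists 0.11. The other 10 lists had means between -0.16 and 0.12 and did not pass camera: epidermal barrier lipid synthesis, keratinocyte junctions, cell cycle, sebaceous gland, dermal matrix, vessels, melanocytes, nerve, red blood cells, and immediate early and heat shock genes. Without 2-week mutant replicate 3, 4 of these 10 passed camera: cell cycle (-0.18), barrier lipid synthesis (0.11), vessels (0.12) and red blood cells (-0.22). No list passed camera with an estimated correlation. The lowest such adjusted p = 0.072 of limma's camera belonged to the antigen presentation, type 2, innate cytokine and macrophage lists, and the other 13 shifted lists had adjusted p = 0.075 to 0.65.

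**Figure D2:**
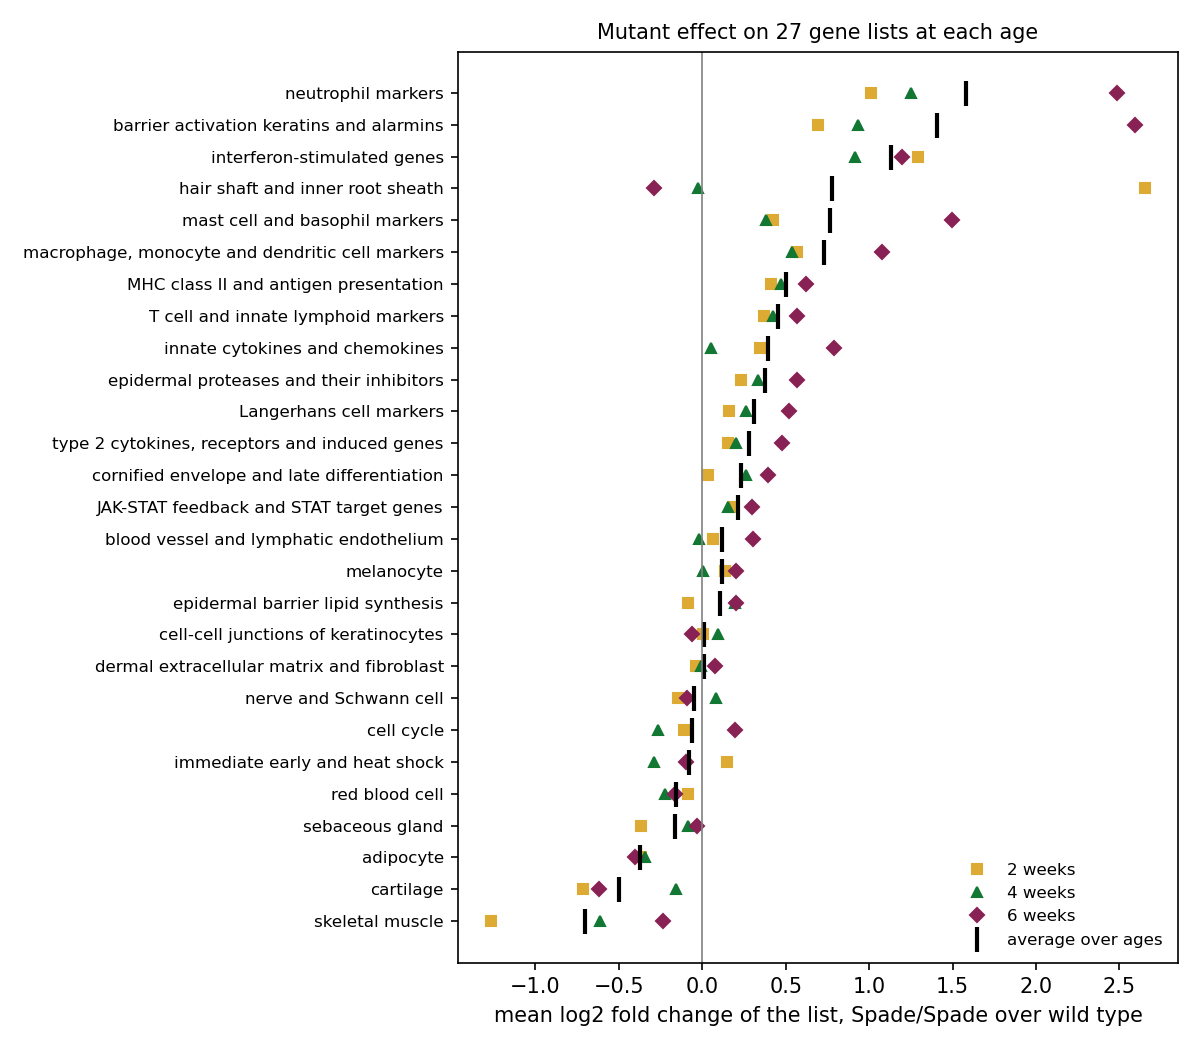
Mean log2 fold change of Spade/Spade over wild type (horizontal axis) for 27 gene lists (vertical axis), with a marker per age and a black tick for the average. Interferon-stimulated genes lie between 0.91 and 1.29 at the 3 ages, neutrophil markers reach 2.49 at 6 weeks, and the hair list lies at 2.65 at 2 weeks and -0.29 at 6 weeks.

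Week by week, the first age asked which changes were already there in young ears. At 2 weeks Krt84 and Mcpt8 were absent on both wild-type arrays by MAS5 and stood at least 5.49 ± 0.79 and 4.21 ± 1.18 above them on the log2 scale (SE, 2 arrays per group). Mcpt8 had a level of 8.02 in mutant replicate 3 and 4.68 in replicate 2, so its value rests more on replicate 3. Stfa2l1, a neutrophil stefin, stood at 4.00 ± 1.17. Usp18 stood at 3.24 ± 0.59 and Ccl8 at 1.62 ± 0.19. The interferon list had a mean of 1.29, the macrophage list 0.56 and the barrier activation list 0.70. Muscle genes had a mean of -1.27. Without 2-week mutant replicate 3 these means were 0.76, 0.27, 0.75 and -0.18 for the interferon, macrophage, barrier activation and muscle lists. No gene passed in limma over all genes (972 at an unadjusted p under 0.05), and 6 of the 538 list genes passed when adjusted over the lists alone. The count was 1187 without 2-week mutant replicate 2 (547 up and 640 down), 2 without 2-week mutant replicate 3 and 1 without either 4-week mutant. The rank product criterion of the study's design called 3 genes: Krt84 and Fetub up, and Gng13 down. Adjusted over the interferon list alone, 18 of its 31 genes passed.

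At 4 weeks the mean differences of the interferon, neutrophil, macrophage and barrier activation lists were positive. None of these 4 lists passed camera with an estimated correlation (adjusted p = 0.26 to 0.35). The 2 mutants spread widely in the neutrophil and barrier activation lists. Krt6b and Oasl2, absent on both wild-type arrays by MAS5, stood at least 3.58 ± 1.62 and 3.13 ± 1.22 above them, Krt16 at 3.49 ± 1.93 and Ifit1 at 3.07 ± 0.91. The interferon list had a mean of 0.91, the neutrophil list 1.25, the macrophage list 0.54 and the barrier activation list 0.93. The adipocyte gene Thrsp stood at -1.84 ± 0.55. In the barrier activation list, mutant replicate 1 had a level of 7.02, against 8.89 in replicate 2 and 6.89 and 7.16 in wild type. In the neutrophil list replicate 1 had 7.07 and replicate 2 had 9.07, against 6.81 and 6.83 in wild type, so both means rest mainly on replicate 2. No gene passed in limma (432 at an unadjusted p under 0.05), and none of the 538 list genes passed when adjusted over the lists alone. Without mutant replicate 1 the count was 10, and without wild-type replicate 3 it was 1. The rank product criterion called 16 genes, 15 up, among them Chil1, Aox4, Klk6, Pde1b, Prss27, Wfdc18, Usp18 and Ifit1, and the keratin gene Krt77 down.

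At 6 weeks 4 genes rose in limma over all genes. Ccl8 was 5.72-fold higher (2.52 ± 0.19, limma adjusted p = 0.0041), and Cd209d 3.07-fold (1.62 ± 0.16, adjusted p = 0.017). Fcer1a, called present on 1 of 2 wild-type arrays, rose 19.8-fold as fitted (4.30 ± 0.47, limma adjusted p = 0.034). Lce3a, a late cornified envelope gene that is induced on barrier injury, was at least 19.1-fold higher (4.26 ± 0.50, limma adjusted p = 0.043). All 29 macrophage markers were positive with a mean of 1.08, and 23 passed adjusted over the list alone. Of the 13 mast cell and basophil markers, all positive, 8 passed adjusted over the list alone, and Mcpt8, absent on both wild-type arrays, stood at least 5.85 ± 1.18 above them. The barrier activation list had a mean difference of 2.59 and the neutrophil list 2.49. Krt6b stood at 8.15 ± 1.62, S100a9 at 4.66 ± 0.83 and S100a8 at 4.51 ± 0.62. In the barrier list, wild-type levels were 8.34 and 8.24 at 2 weeks and 6.63 and 7.11 at 6 weeks. Mutant levels were 8.93 and 9.04, then 9.26 and 9.67. The larger difference at 6 weeks thus came more from lower wild-type levels than from higher mutant levels. The 2-week arrays lie in a range of array numbers that holds no older array. Levels compared between these ages therefore cannot be told from a range difference. In the barrier list 12 of 24 genes passed adjusted over the list alone, in the neutrophil list 3 of 7, in the innate cytokine list 6 of 16 and in the interferon list 17 of 31. Btc stood at -4.77 ± 0.76 (adjusted p = 0.096 in limma).

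Of the 4 calls at 6 weeks, 3 are among the 538 list genes, of which 57 passed when adjusted over the lists alone, and 1426 of all genes had an unadjusted p under 0.05. The rank product criterion called 53 genes, 48 up, of which 3 were among the 4 limma calls. All 15 genes it called up at 4 weeks were also called up at 6 weeks, and Krt84 and Fetub were called at all 3 ages. Independent lists would share 0.06 genes, but only if every gene were equally likely to be called. In the simulation each gene's own spread changed which genes were called, so 0.06 is no fair baseline for the overlap. The limma count of 4 fell to 0 on MAS5 signals, with a term for sex, or without 6-week wild-type or mutant replicate 3. It was 1 or 2 without 2-week wild-type replicate 1 or 2, 4-week wild-type replicate 1 or 3, 6-week wild-type replicate 1 or 6-week mutant replicate 4, and 36 to 44 without any 1 of the 2-week or 4-week mutants.

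**Figure D3:**
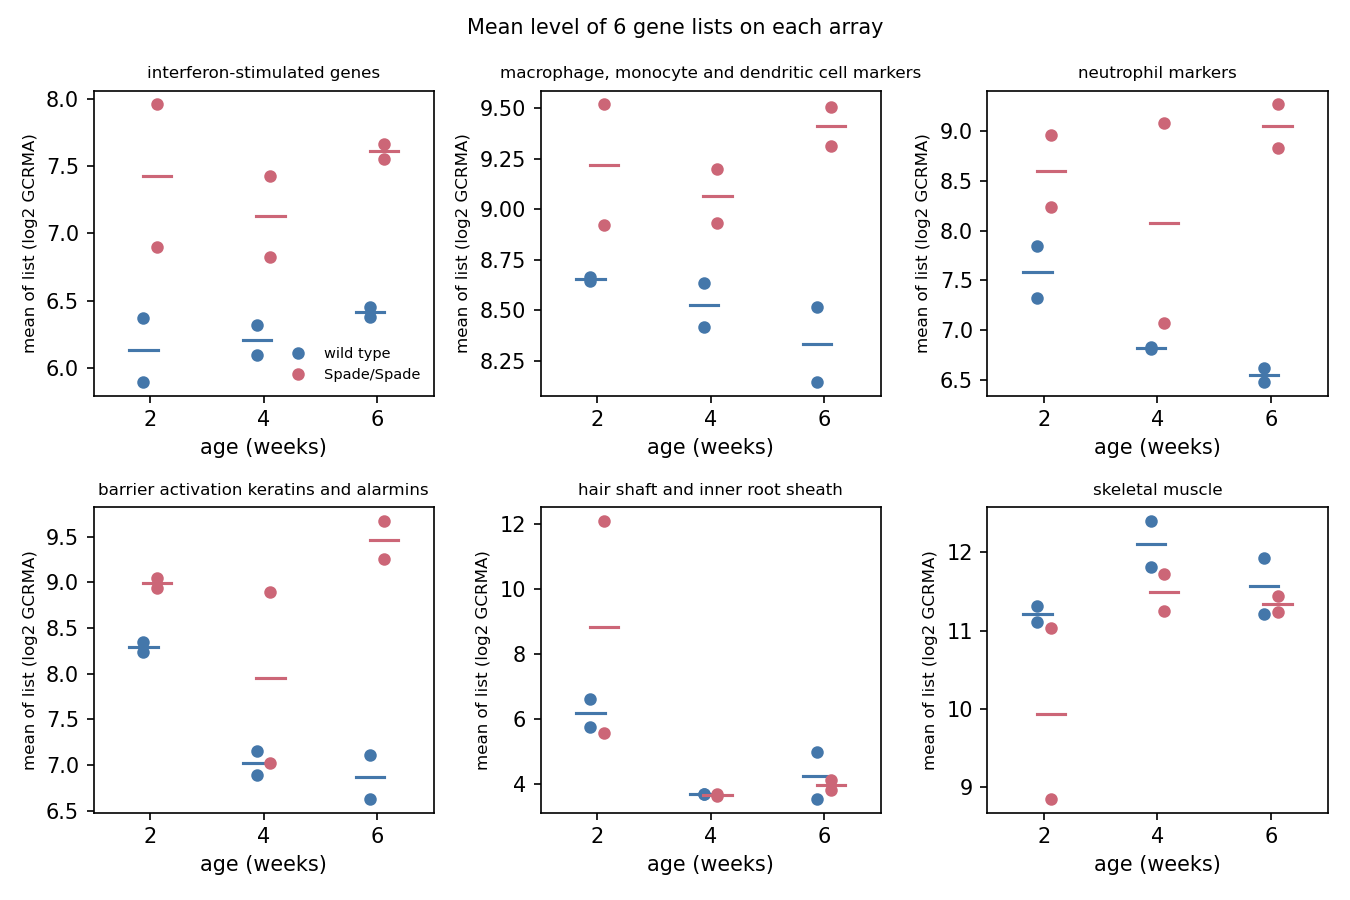
Mean log2 GCRMA level of 6 gene lists (vertical axis) on each array against age in weeks, with a point per array and a bar at the mean of each group of 2. The 6-week mutants lie at 9.26 and 9.67 in the barrier activation list against 6.63 and 7.11 in wild type, and 2-week mutant replicate 3 lies at 12.1 in the hair list and 8.85 in the muscle list.

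Whether the mutant effect differed with age was tested directly. Fcer1a differed by 4.30 at 6 weeks as fitted, and at 2 weeks lay at the floor on both wild-type arrays and 1 of 2 mutants. S100a8 differed by 4.51 at 6 weeks and 0.51 at 2 weeks, Btc by -4.77 and -1.40, and Usp18 by 2.80 and 3.24. No gene passed in limma for the difference between the effects at 6 and 2 weeks (654 at an unadjusted p under 0.05), 4 and 2 weeks (331) or 6 and 4 weeks (351). None of the 538 list genes passed when adjusted over the lists alone in any of these. For 6 against 2 weeks the count was 372 without 2-week mutant replicate 2.

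Wild-type ears changed with age from 2 to 6 weeks. Akr1c18, a hydroxysteroid dehydrogenase, was at least 144-fold higher at 6 weeks (7.17 ± 1.13), and the cytochrome P450 gene Cyp2e1 at least 54.4-fold (5.77 ± 0.82). Muscle myosins exchanged: the slow-fibre genes Myl2 and Myh7 rose (5.72 ± 0.59 and at least 4.49 ± 0.94 on the log2 scale), while Myh8, the perinatal myosin, fell by 5.11 ± 0.85. Igf2bp3, a fetal RNA-binding protein, fell by at least 4.72 ± 0.53, and Adam12, Slc38a4 and Ddit4 fell by 3.91 ± 0.82, 3.34 ± 0.39 and 3.15 ± 0.49. Of 16 adipocyte genes 9 rose and 12 passed upward adjusted over the list alone, with a mean of 1.67. Among them were the fat hormone gene Retn (9.35-fold), Lep, which MAS5 called absent at both ages and for which no fold is given, the lipid droplet gene Cidec and Pck1. Of 11 melanocyte genes 6 fell, with a mean of -1.57, including the pigment genes Oca2, Tyrp1, Mlana and Dct (-2.97 ± 0.43, -2.29 ± 0.34, -2.10 ± 0.41 and -2.09 ± 0.30). Of 30 dermal matrix genes 5 fell, among them the collagen crosslinking enzyme gene Lox (-1.70 ± 0.37) and Fbln2 (-1.27 ± 0.22). The endothelial genes Pecam1 and Tie1 fell by 1.84 ± 0.39 and 1.54 ± 0.27. The barrier activation list was also lower at 6 weeks, at 6.63 and 7.11 against 8.34 and 8.24 at 2 weeks. Cartilage genes moved both ways: the collagen genes Col2a1 and Col9a2 fell by 2.57 ± 0.58 and 1.95 ± 0.45, while the transcription factor gene Sox5 and the secreted factor gene Cytl1 rose by 1.89 ± 0.30 and 1.25 ± 0.26, and 13 of 21 were positive.

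In limma 578 genes passed, 397 up and 181 down, and 69 of the 538 list genes passed adjusted over the lists alone, against 49 over all genes. The adipocyte, melanocyte and dermal matrix shifts were lost with an estimated correlation (adjusted p = 0.41 each). The median of all genes rose by 0.10 on the log2 scale between these ages, and after median centring the calls were 195 up and 247 down (442 in all), so the share of higher calls moved from 68.7% to 44.1%. The count was 49 with a term for sex, 183 on MAS5 signals, 217 with only the groups compared and 371 without a filter on low values, and 1595 over all probe sets and 1848 with array weights. The 2-week arrays all lie in 1 range of array numbers that holds no older array, so age and range cannot be told apart here. The count was 0 without either 2-week wild-type array, 23 without 6-week wild-type replicate 1, 167 without 6-week wild-type replicate 3, 289 without either 6-week mutant, 328 and 339 without 4-week mutant replicate 1 or 2, and 1495 and 1499 without 2-week mutant replicate 3 or 2.

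From 4 to 6 weeks no gene passed in wild type (limma, 852 at an unadjusted p under 0.05) and none of the 538 list genes passed adjusted over the lists alone. By camera 11 lists shifted: melanocyte (-0.68), skeletal muscle (-0.53), vessel (-0.45), dermal matrix (-0.38), cell cycle (-0.38), innate cytokine (-0.26), cornified envelope (-0.23), protease (-0.20), macrophage (-0.20) and barrier lipid (-0.09) genes, and antigen presentation (0.18). None of them passed with an estimated correlation (adjusted p = 0.67 to 0.79 in camera). In the muscle list wild-type replicates 3 and 1 had 11.8 and 12.4 at 4 weeks, and 11.9 and 11.2 at 6 weeks. In the melanocyte list they had 8.56 and 8.87, then 8.38 and 7.70. Both falls thus rest mainly on the arrays numbered 1, of which the 6-week one lacked Xist signal. For the mutant effect, other splits of the arrays gave a median of 12 lists by camera. A count of 11 therefore does not by itself show a change with age.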

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

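Tests on degraded RNA, on array number ranges, on sex and on the share of muscle were chosen after the result was seen; the others were written down before. Of the lists, 14 differed by camera between the mutant effect at 6 weeks and that at 2 weeks, and this difference drew attention to them. With a correlation estimated within each list none held (adjusted p = 0.52 or more in limma).

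Without 2-week mutant replicate 3, the macrophage list (0.51 on the log2 scale, adjusted p = 2.0e-06 in limma) held at 0.81. The mast cell and basophil list (1.07, limma adjusted p = 9.0e-06) held at 1.32, and the barrier activation list (1.90, limma adjusted p = 1.2e-05) at 1.84. The cell cycle list (0.31, limma adjusted p = 0.028) stood at 0.66 and the innate cytokine list (0.44, limma adjusted p = 0.036) at 0.54, both still past the threshold. The hair list (-2.94, limma adjusted p = 4.6e-07) and the muscle list (1.03, limma adjusted p = 9.6e-05) did not hold, at 0.31 and -0.05. Other lists lost the call with 1 array fewer but several kept their size: neutrophil markers went from 1.47 to 1.12, cornified envelope genes from 0.35 to 0.31, barrier lipid genes from 0.29 to 0.27 and antigen presentation from 0.21 to 0.23. Type 2 genes went from 0.33 to 0.25, immediate early genes from -0.25 to -0.19 and sebaceous genes from 0.33 to 0.05.

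A single ear sample, 2-week mutant replicate 3, stood apart, with a median correlation over genes of 0.906 with the other arrays, against at least 0.967 for every other array, and with high hair shaft genes and low muscle genes. The beta-actin signal ratio of 1.58 was above the 1.45 to 1.49 of the other 2-week arrays but below the 1.63 to 2.22 of all 8 older arrays, none of which stood apart, so this ratio gives little ground for degraded RNA, which stays open only because age and ratio go together. In MAS5 signals the hair list stood 4.24 ± 0.22 (SE over genes) above the other 2-week arrays, against GCRMA processing. Its interferon list lay 1.58 above the higher wild-type array, where the wild-type arrays lay 0.48 apart, against a wild-type ear labelled as mutant. Its cell cycle and melanocyte lists lay 0.19 and 0.39 above the highest other 2-week array, as more growing hair follicle in this ear would give. Pigment genes went both ways, however. Dct and Pmel (12.6 and 11.7) lay above the other 2-week arrays. Oca2, Tyrp1 and Mlana (7.13, 11.8 and 10.2) lay below 2-week wild-type replicate 1 (7.30, 12.1 and 10.7). More growing follicle therefore stays possible only, and may reflect the hair cycle or where the ear was sampled.

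Of the 4-week mutants, replicate 1 lay nearer wild type, at 7.02 in the barrier activation list against 8.89 in replicate 2. Its interferon list still lay 0.50 above the higher wild-type array, with 0.22 between the wild-type arrays, against a wild-type ear labelled as mutant. Other wrong labels were not tested. The number of array number ranges that part the 2 mutants is 0, against a range effect. The Xist signal was missing on this array and on 6-week wild-type replicate 1, as in male mice. That wild-type array lay 0.48 above its replicate, where 1.87 parts the mutants, but 1 array of another age excludes nothing, so a sex effect stays open.

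Interferon-stimulated and leukocyte lists had higher means in the mutants. A smaller share of muscle would raise dermal matrix genes alike, but the interferon list exceeded that list by 1.13 ± 0.15 (SE over genes). Genes within these lists are correlated (estimated at 0.54 and 0.51), so this error does not measure the spread between samples. The dermal matrix list's own mean difference was 0.0079. Within 1 range of array numbers the interferon list's difference was at least 1.03, against a range effect. Both mutant arrays lay above both wild-type arrays in the interferon list at 3 of 3 ages, as a genotype effect present from 2 weeks on would give. The exact permutation rests on this same separation, so these are not separate evidence. Whether more leukocytes entered the ear or resident cells changed their expression was not tested, since whole tissue holds both.

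Other splits of the arrays within age were drawn to ask how often they give as much. The real split gave 77 genes and was the only 1 of 100 to reach that number; the highest other split gave 1 gene. For lists, 23 of 100 splits gave at least 17 by camera, the highest 20 and the median of the others 12. Camera's list count with its preset correlation therefore does not tell the genotypes from other splits.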

How the results depend on the processing

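The sex term, array weights and the exact permutation were chosen after the data were examined. Leaving out each array in turn was planned. Apart from Jak1, the single genes and lists followed had passed the threshold on these same arrays, so a kept direction is weak support. Under the alternatives that left out no single array, 740 gene values kept their direction and side of the threshold. Another 298 kept only their direction and 2 reversed. For lists these were 90, 27 and 1. The fit of only the groups compared, with fewer arrays, is counted here. With arrays left out, the gene values were 497, 595 and 0, and the list values 203, 0 and 1.

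The rank product criterion gave 3 genes at 2 weeks, 16 at 4 weeks and 53 at 6 weeks; for the ages together it gave 110, of which 41 were among the 77. With a 2-fold minimum 42 genes remained on average and 280 in wild type from 2 to 6 weeks. No filter on low values gave 6, 10 and 24 genes at 2 weeks, at 4 weeks and on average, 5 for the effect at 6 against 2 weeks, and 371 and 2 in wild type from 2 and from 4 to 6 weeks; more genes were then tested. A filter at 6 left 2 genes at 6 weeks. The mean of probe sets gave 48 on average, and all probe sets gave 2 at 6 weeks, 43 on average and 1595 in wild type from 2 to 6 weeks. With the mean of probe sets Tapbp and Tnc reversed in wild type from 2 to 6 weeks, to -0.35 and 0.019 on the log2 scale. MAS5 signals gave 4 at 4 weeks, 0 at 6 weeks, 40 on average and 183 in wild type from 2 to 6 weeks, and 23 of the 40 were among the 77. Median centring gave 8 and quantile normalization 10 genes at 6 weeks. No trend in the prior gave 1 at 2 weeks. The cause was not tested for any of these unless stated.

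Fitting only the groups compared gave 11 genes at 6 weeks and 217 in wild type from 2 to 6 weeks, with fewer arrays. With array number range as a block there were 2 genes at 6 weeks and 24 on average. In this design the block leaves the average fold unchanged and alters only its error. It could not be run for wild type from 2 to 6 weeks, where age and range coincide, and a fit of only the groups compared equals the full fit for the average. Replicate numbers recur between genotypes. Deviations of arrays with the same number correlated across genes at -0.12, 0.19 and 0.25 at 2, 4 and 6 weeks. The consensus correlation of replicate numbers within age was 0.43. Whether the numbers pair samples cannot be told from these values, since the labels do not name animals. With a random replicate block within age 238 genes passed on average, and with a fixed one 0 in wild type from 4 to 6 weeks. The sex term gave 0 genes at 6 weeks and 49 in wild type from 2 to 6 weeks, and array weights gave 24 and 1848. For lists, 0 passed with an estimated correlation, 9 by fry and 7 by the exact permutation, against 17. The list of hair shaft and inner root sheath, on average over ages, reversed to -1.03 with muscle level as a covariate and to -0.31 without 2-week mutant replicate 3, and lay between -0.31 and 1.86 over all arrays left out.

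Leaving out each array in turn gave 0 to 1187 genes at 2 weeks, 0 to 10 at 4 weeks, 0 to 44 at 6 weeks and 2 to 1070 on average. It gave 0 to 372 for the effect at 6 against 2 weeks, 0 to 1499 in wild type from 2 to 6 weeks, 0 throughout from 4 to 6 weeks, and 17 to 21 lists. The array left alone in its group is then assumed to vary like the other groups. The highest counts came without a 2-week or 4-week mutant array. Arrays give no depth to weigh, and 30.5% to 32.0% of probe sets on each lay at the floor. There a fold is a bound only if the true level was no higher than the floor value. With arrays of both groups at the floor it has no bound.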

Other observations

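The test on the genes around Jak1 was chosen after the result was seen. Krt84 was the only call in the hair shaft list. It stood at 9.07 and 9.16 on the log2 scale in the 2-week mutants, 3.80 and 6.98 in the 4-week mutants and 6.05 and 6.61 in the 6-week mutants, against 2.19 to 3.87 in wild type. None of the other 30 genes of the hair list passed, and Krt81 stood at 1.21 ± 1.11. The 4-week mutant value of 3.80 lay within the wild-type range, and the source of Krt84 in the ear was not tested.

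The mutant effects of different ages shared no arrays, and correlated across genes at 0.369 between 2 and 4 weeks, 0.378 between 2 and 6 weeks and 0.549 between 4 and 6 weeks.

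Genes next to Jak1 would differ if linked variants came with the allele from another strain. Of the 100 tested genes nearest to Jak1 in gene order, 18 had an unadjusted p under 0.05 on average, or 18.0% against 14.8% of other genes (two-sided Fisher's exact p = 0.395). The odds ratio of 1.26 had a 95% interval of 0.712 to 2.13, and 0 of these genes passed the adjusted threshold, so the data cannot tell.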
